A study of Mus musculus with 10 samples.

How the data were processed

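Messenger RNA levels were measured by RNA sequencing in 10 samples of sorted mouse retinal cells, 5 CD36-positive and 5 CD36-negative, each a part of the live CD11b-positive, CD45-intermediate gate, per the labels. The labels state that libraries followed standard Illumina protocols. The deposited table held expected counts per gene symbol (estimated counts that need not be whole; 91.9% of values were whole numbers), not normalized, with 1 column per sample. The submitters' processing notes list fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0 and StringTie 1.3.1 and the mouse build mm10, per the submitters' processing notes, without saying what each tool did; the program that made the counts is not given in the sources used here. Single-cell and spatial data of the series were not analysed here.

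Of 22008 lines after the header, 8 that did not hold 10 values and a symbol and 131 that repeated an earlier line in full were dropped, leaving 21869 genes, of which 2033 were at 0 in every sample. The damage followed blocks of fixed length in the file, and some genes at the seams are not analysed here. Of the symbols, 27 had been turned into dates by a spreadsheet, and no result is reported for them. For 3 symbols on 2 lines with different values, Plin2 among them, the line with the higher mean kept the symbol. Expected counts were rounded to whole numbers before testing.

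Samples were grouped by the description label, and replicate numbers are those of that label; the titles number the samples differently. Genes were kept with edgeR's filterByExpr by group (minimum count 10), scaled by TMM, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 with group as the only term and Benjamini-Hochberg adjustment at 0.05; 11596 genes were tested. Confidence intervals are 95% intervals from the standard error and the test's degrees of freedom. CPM values use TMM-scaled library sizes. From 39 gene lists written before the data were examined, the 36 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and also an estimated one, and adjusted over lists. The mitochondrially encoded list had 0 tested members and the B cell list 3, and the sex-linked genes served only as a check. Of the 36 lists 13 passed, and 4 of these with the estimated correlation. With fry, which tests whether the genes of a list move one way on balance, the neutrophil, T and NK cell, dendritic cell and monocyte lists gave adjusted p of 2.34e-06, 9.37e-05, 1.88e-05 and 4.69e-05. Some lists past camera did not pass fry: photoreceptors (fry adjusted p = 0.132), type I interferon (0.162), oxidative phosphorylation (0.0892) and macrophages of vessels and borders (0.0749). Fatty acid synthesis (0.00211), lipid droplets (0.0194) and inner retinal neurons (0.0407) passed fry but not camera. The mixed form of fry, which takes either direction, gave an adjusted p of 3.46e-09 for the inflammasome list. It gave the same value for the lipid droplet, scavenger receptor and phagocytosis lists. Most lists passed 0.05 in this form, so passing it is not particular to the inflammasome list.

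The rule for the genes named was written before the data were examined: Cd36, Itgam, Ptprc, Nlrp3 and Il1b always; the 2 members with the smallest p of each list with a member past the threshold or past it as a list; and up to 6 genes per direction with the largest log2 fold change among those past the threshold with an average log2 CPM of at least 3 and a gene name. It gave 70 genes, not all of which are described, and some results are not reported here. Folds against a group without counts use a floor of 3 counts over the group, and intervals for 1 to 3 counts are exact binomial; both cover counting error only, since reads amplified by PCR are not independent molecules. One library's floor of 3 counts corresponds to 0.226 to 0.6 CPM.

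The test was run on simulated data, with counts drawn for these genes at these library sizes and dispersions (5 simulations, about 11376 genes tested, 200 genes changed). It recovered 36.1% of genes changed 2-fold and 80.5% of those changed 4-fold, 4.4% of calls were false, and a planted list of 25 genes was called in 5 of 5 simulations. These simulations drew genes independently of each other, so they do not test the preset correlation. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 22.1 to 109).

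Alternatives planned before the data were examined were DESeq2 size factors, no filter and a stricter filter (10 CPM in 5 samples), replicate numbers of either label as a block, each sample left out, limma voom with sample quality weights, the number of detected genes as a covariate, the DESeq2 1.42.0 Wald test, an adjusted p of 0.01, a test against a log2 fold change of 1, and the estimated correlation. A change of pseudocount was planned for a normalized unit and does not apply to counts. Those added after the data were seen were offsets for GC content and transcript length (GENCODE annotation of GRCm38, the assembly of mm10; 96.2% of tested genes had both), the same from a robust fit because the first moved the median of all genes, the level of Y-linked genes as a covariate and as 2 subsets, CD36-positive libraries 1 and 3 left out, and lines at block edges left out. Symbols of 96% of tested genes matched 1 gene of that annotation. Other splits of the samples were drawn 100 times of 126.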

Results

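RNA sequencing counts were available for 10 libraries of retinal cells from mice. Live cells with CD11b and an intermediate level of CD45, a gate the labels name microglia, had been sorted by flow cytometry. The gate was divided by the scavenger receptor CD36 into CD36-positive cells (5 libraries, numbered 1, 2, 3, 4 and 7) and CD36-negative cells (5 libraries, numbered 1, 2, 4, 7 and 8). Per the labels' protocol, mice received 20 mg/kg of sodium iodate, a toxin of the retinal pigment epithelium, or saline, and eyes were taken 7 days later. The labels do not say which of these treatments the 10 sorted samples had, so no treatment was compared. Total counts per library ran from 5001692 to 13250984. Between 13531 and 15089 genes had a count above 0. CD36-positive libraries 1 and 3 were the shallowest, with totals of 5001692 and 6904523. On principal components of log2 CPM the first component (35.9% of the variance) separated the groups, while CD36-positive library 1 stood apart on the second (15.9%) and library 3 on the third (12.3%).

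**Figure D1:**
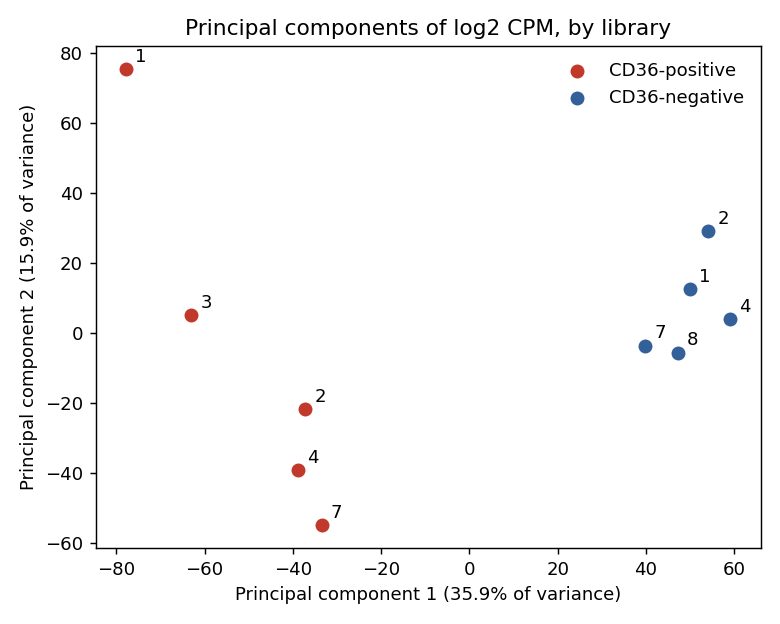
Libraries on the first and second principal components of log2 CPM (axes give each component's share of variance in percent); points are libraries, coloured by group and numbered as in the labels. All 5 CD36-positive libraries lie below 0 and all 5 CD36-negative libraries above 0 on the first component, and CD36-positive library 1 lies highest on the second, at 75.4.

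The comparison of CD36-positive with CD36-negative cells asks how the 2 parts of the gate differ, with lipid handling and the Nlrp3 and IL-1β pathway named in the series title. Cd36 itself, the gene of the sorted protein, was at 219 ± 39.9 CPM in CD36-positive and 50.3 ± 5.51 CPM in CD36-negative libraries (mean ± SD, n = 5 each), a log2 fold change of 2.12 (SE 0.18, edgeR quasi-likelihood adjusted p = 1.45e-06). Every CD36-positive library lay above every CD36-negative one. Il1b, which encodes the cytokine IL-1β, was lower in CD36-positive cells, at 48.5 ± 20.0 against 140 ± 41.5 CPM (log2 fold change -1.53, SE 0.27, edgeR adjusted p = 0.00166). It was lower in 5 of 5 CD36-positive libraries than in any CD36-negative library. Nlrp3, the inflammasome sensor, did not pass the test (13.3 ± 5.12 against 10.1 ± 2.66 CPM, log2 fold change 0.40, 95% confidence interval -0.39 to 1.19, edgeR adjusted p = 0.597). The genes of the other sort markers did not pass either: Itgam (CD11b) had a log2 fold change of -0.20 (interval -0.74 to 0.34) and Ptprc (CD45) one of 0.13 (interval -0.30 to 0.56). On GRCm38, Cd36 lies on chromosome 5 from 17781690 to 17888801, Il1b on chromosome 2 from 129364570 to 129371139, and Nlrp3 on chromosome 11 from 59541568 to 59566956. Each is annotated as protein coding.

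**Figure D2:**
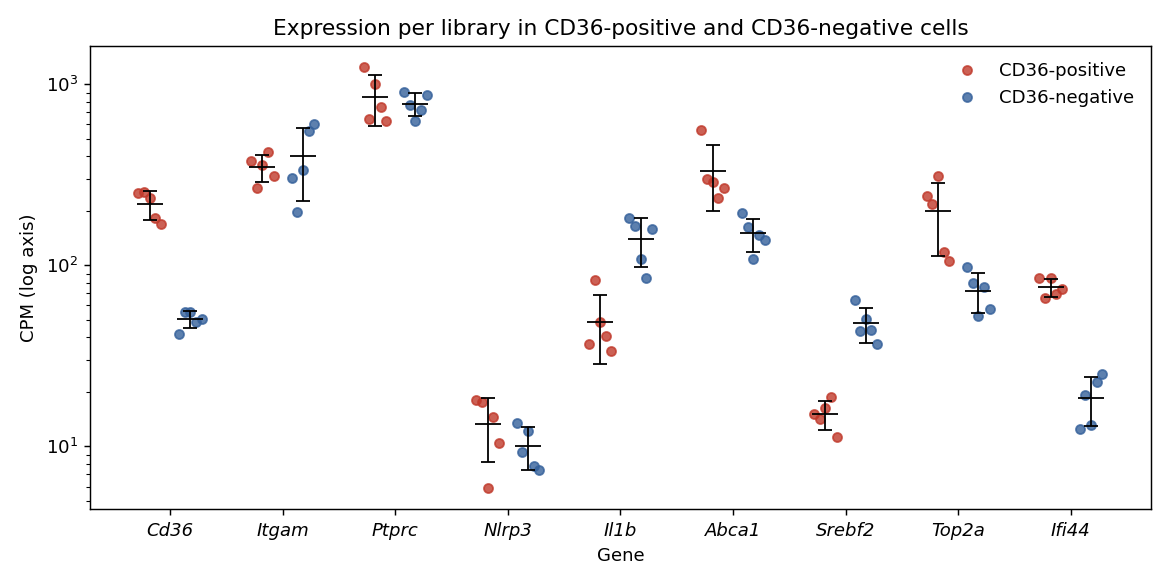
CPM per library (log axis) of 9 genes in CD36-positive and CD36-negative cells; points are libraries, horizontal bars the mean and error bars 1 SD (n = 5 per group). Cd36, Abca1, Top2a and Ifi44 lie higher and Il1b and Srebf2 lower in CD36-positive libraries, while Nlrp3, Itgam and Ptprc overlap.

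Across 11596 genes tested, 303 were higher and 550 lower in CD36-positive cells at an adjusted p under the 0.05 threshold of edgeR's quasi-likelihood test. Of the 22 tested members of the inflammasome and IL-1 list, 1 rose, 3 fell and 18 did not pass (1 and 4 adjusted over the list alone). The one that rose was Casp1, the protease that cleaves the IL-1β precursor (log2 fold change 0.64, SE 0.17), and besides Il1b the decoy receptor gene Il1r2 (-5.51, SE 0.53) and Txnip (-0.59, SE 0.16) fell. Il1r2 is also in the neutrophil list, of which 10 of 12 members fell. Casp1 and Txnip were chosen after their values were seen. As a list these genes did not pass (camera adjusted p = 0.961), and the median (0.13) and mean (-0.28) of their log2 fold changes differed in sign. Of 25 NF-kB cytokines and chemokines, 4 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.738). Ccl12, a monocyte chemoattractant, rose by 1.59 and the NF-kB subunit gene Relb fell by 1.45 on the log2 scale. Ccl7 had the highest rise among the genes named by size, 2.83. CD36-positive library 3 held 303 CPM of it against 19.4 to 37.0 in the other 4, and without that library the log2 fold change was 1.2 and did not pass.

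Genes of lipid handling moved in both directions. In the list of scavenger receptors and lipid uptake, 4 of 21 tested members rose, 2 fell and 15 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.391). Besides Cd36, the members that rose were the scavenger receptor genes Msr1 (1.46, SE 0.22) and Stab1 (0.61, SE 0.16) and Lpl, lipoprotein lipase (0.97, SE 0.20). Scarb1 (-1.16, SE 0.23) was among those that fell. Cholesterol biosynthesis genes fell in 5 of 23 members and rose in 0 (9 and 0 adjusted over the list alone; median log2 fold change -0.71). Among these were Srebf2, the transcription factor that drives the pathway (15.1 ± 2.73 against 47.7 ± 10.3 CPM, log2 fold change -1.66, edgeR adjusted p = 0.000214), and the enzyme genes Cyp51 (-1.23), Sqle (-2.29) and Mvd (-1.71). The list passed with the preset correlation between genes (camera adjusted p = 2.64e-06) but not with an estimated one (adjusted p = 0.131 with an estimated correlation). Without CD36-negative library 1 or 4, 3 members fell, as after a correction for GC content and transcript length (5 with a robust fit of it), and Sqle was at -3.0 without CD36-positive library 7. Markers of neutrophils, T and NK cells, dendritic cells and monocytes were lower as well, with medians of -5.72, -3.58, -2.81 and -2.24. Of 18 cholesterol efflux and LXR target genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.735, median 0.25, mean -0.06). The sterol exporter gene Abca1 rose by 1.14 (SE 0.23) and Ch25h, cholesterol 25-hydroxylase, by 1.00, whereas Pltp fell by 1.40 and Nr1h2, which encodes LXRβ, by 1.05. Of 19 lipid droplet genes 0 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.188). Lipe, hormone-sensitive lipase, fell by 1.09. G0s2 had no count in the CD36-positive libraries against 397 in the CD36-negative ones, at least 109-fold lower with a floor of 3 counts over the group; it is also in the neutrophil list, of which 10 of 12 members fell. Plin2, a coat protein gene of lipid droplets, did not pass (207 against 184 CPM, log2 fold change 0.17). Msr1, Stab1, Scarb1, Cyp51, Sqle, Mvd, Ch25h, Nr1h2 and Plin2 were chosen after their values were seen. No member of the fatty acid oxidation (25 tested, camera adjusted p = 0.509) or fatty acid synthesis list (14 tested, camera adjusted p = 0.116) passed edgeR's test, over all genes or adjusted over the list alone.

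Marker genes of other leukocytes were lower in CD36-positive cells. Of 12 neutrophil markers 10 fell (11 adjusted over the list alone; median log2 fold change -5.72). S100a9, an abundant neutrophil transcript, was at 2.52 ± 4.30 against 117 ± 66.3 CPM; it was chosen after its values were seen. Retnlg had no count in CD36-positive libraries and 4123 counts in CD36-negative ones, at least 1130-fold lower. Of 15 T cell and NK cell markers 10 fell (11 adjusted over the list alone; median -3.58). Among them were the cytotoxic granule genes Nkg7 (-6.50, SE 0.67) and Gzmb (-7.44, SE 0.89), with 18 and 7 counts over the CD36-positive group. Without CD36-positive library 2, Nkg7 was at -7.31 and Gzmb at -9.51, and Gzmb was at -6.83 without CD36-negative library 1. The list's median was -4.75 without CD36-positive library 2 and -4.93 without library 3 (20 members tested in each), and -2.79 without CD36-negative library 1, where 7 of 15 fell, as without CD36-negative library 2. With the filter of 10 CPM in 5 samples, 4 of 5 tested members fell (median -2.26). In libraries of low and of high Y-linked expression, 11 of 19 and 10 of 21 fell (medians -6.87 and -3.82). Dendritic cell markers fell in 12 of 18 members and rose in 1 (13 and 1 adjusted over the list alone; median -2.81). Clec10a was at -3.75 (SE 0.32) and the integrin gene Itgae at -7.44 (SE 0.68; -8.73 without CD36-positive library 3), while Bst2, also an interferon-induced gene, rose by 0.97. Monocyte markers fell in 13 of 22 members and rose in 1 (14 and 3 adjusted over the list alone; median -2.24). S100a6 was at -4.93 (SE 0.31) and S100a4 at -4.72 (SE 0.46). The member that rose was Ms4a4c (0.81, SE 0.18; it did not pass after the correction for GC content and transcript length, at 0.58), and Ccr2, a chemokine receptor gene, did not pass (413 ± 174 against 408 ± 64.3 CPM, log2 fold change 0.01, interval -0.48 to 0.51); both were chosen after their values were seen. These 4 lists passed with the preset correlation (camera adjusted p of 1.29e-16, 3.20e-11, 4.88e-11 and 2.62e-09, in this order). They also passed with an estimated one (adjusted p = 0.0116, 0.0399, 0.0224 and 0.0399 with an estimated correlation). Genes of MHC class II presentation fell in 9 of 14 members and rose in 0 (10 and 1 adjusted over the list alone; median -1.97, camera adjusted p = 5.88e-09, adjusted p = 0.151 with an estimated correlation). H2-Oa (-3.92, SE 0.30) and H2-DMb2 (-3.50, SE 0.33) had the smallest p. With lines at block edges left out, 6 of 11 tested MHC class II members fell, with a median of -1.35. In that fit 12 of 21 tested monocyte members fell and 1 rose, with a median of -1.56. The largest falls among genes of at least 3 in average log2 CPM included Apol7c, Ffar4, Ccl17 and Ffar2, each with 1 to 3 counts over the CD36-positive group. Per total count, Ffar4, a fatty acid receptor gene, was 1120 times higher in CD36-negative cells (95% counting interval 200 to 44100) and the chemokine gene Ccl17 603 times (167 to 4980).

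**Figure D3:**
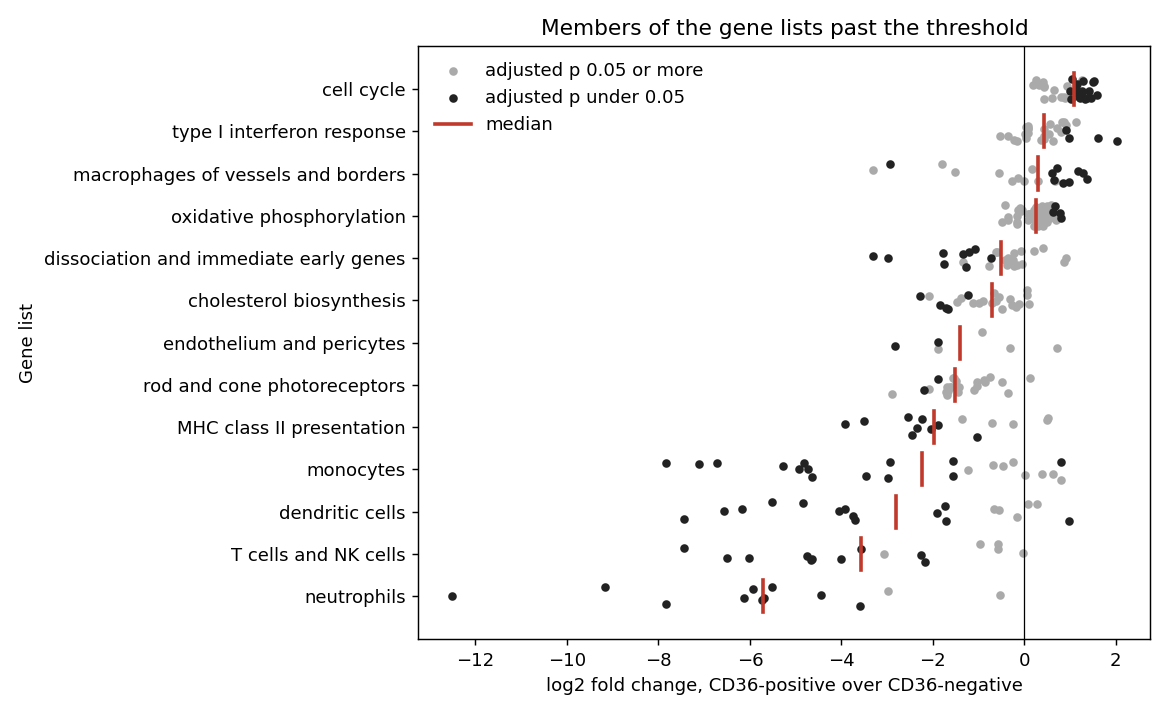
Log2 fold change (CD36-positive over CD36-negative, x axis) of the tested members of the 13 gene lists past the threshold (y axis); points are genes, dark where the adjusted p is under 0.05, and red bars are medians. Neutrophil members have the lowest median, -5.72, and cell cycle members the highest, 1.09.

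Cell cycle genes were higher in CD36-positive cells: 19 of 34 members rose and 0 fell (24 and 0 adjusted over the list alone; median 1.09, camera adjusted p = 1.44e-12, adjusted p = 0.330 with an estimated correlation). Stmn1 was at 319 ± 57.3 against 156 ± 36.6 CPM (log2 fold change 1.03) and Top2a, DNA topoisomerase II, at 199 ± 86.8 against 72.5 ± 18.3 CPM (1.45). Without CD36-positive libraries 1 and 3, the libraries that stood apart, 4 members rose and the median was 0.78. With 1 library left out, 7 rose without CD36-negative library 4, 8 without CD36-positive library 3, 9 without CD36-negative library 8, and 12 without CD36-positive library 2 or CD36-negative library 2 or 7. In the smaller subsets of high and of low Y-linked expression, 4 and 3 members rose, with medians of 1.01 and 0.62. Type I interferon genes rose in 4 of 28 members and fell in 0 (8 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 0.000360, adjusted p = 0.622 with an estimated correlation). These were Ifi44 (2.03, SE 0.23), Bst2 (0.97), Cxcl10 (1.60) and Ifi204 (0.90). Cxcl10 and Ifi204 were chosen after their values were seen. Members of this list that rose numbered 8 with the DESeq2 Wald test and 11 with the Y-linked level as a covariate, and the list did not pass with the number of detected genes as a covariate (median 0.30). Oxidative phosphorylation genes rose in 4 of 49 members, among them Atp5k (0.80) and Ndufa4 (0.67), and fell in 0 (6 and 0 adjusted over the list alone; median 0.26, camera adjusted p = 6.55e-05, adjusted p = 0.622 with an estimated correlation). In edgeR 0 members passed without CD36-positive library 2 or 3, without CD36-negative library 1, 7 or 8, or without both libraries that stood apart, and 1 passed without CD36-negative library 4. The DESeq2 Wald test gave 7, and edgeR after a correction for GC content and transcript length gave 13 (4 with a robust fit of it). Markers of macrophages of vessels and borders rose in 8 of 19 members and fell in 1 (9 and 4 adjusted over the list alone). Ms4a7 was at 799 ± 116 against 310 ± 121 CPM (1.37, SE 0.25) and Ms4a6b at a log2 fold change of 0.98. That list stood near the threshold (camera adjusted p = 0.0495, adjusted p = 0.569 with an estimated correlation), and its median (0.30) and mean (-0.09) differed in sign. It did not pass in 8 of 10 fits that left out 1 library each; 4 members rose without CD36-negative library 4 or 7, and 5 without CD36-positive library 2 or CD36-negative library 2 or 8.

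Immediate early genes, which cell dissociation can induce, fell in 9 of 26 members and rose in 0 (10 and 1 adjusted over the list alone; median -0.52, camera adjusted p = 5.33e-05, adjusted p = 0.200 with an estimated correlation). Btg2 was at -1.22 (SE 0.17) and Dusp1 at -1.78 (SE 0.25). After the correction for GC content and transcript length 7 members fell, 1 rose and the list's median was -0.22, against 0.162 for all genes; with the robust fit 7 fell and the medians were -0.32 and 0.056. Of 24 photoreceptor genes 2 fell, among them Nr2e3 (4.44 ± 4.30 against 20.6 ± 17.0 CPM). Adjusted over the list alone 12 fell (median -1.52, camera adjusted p = 1.62e-05, adjusted p = 0.622 with an estimated correlation). Over all genes 0 fell in edgeR after the correction, or without CD36-positive library 1, 3, 4 or 7 or CD36-negative library 2, 4 or 8, whereas 11 fell without CD36-positive library 2 (median -2.15) and 5 without CD36-negative library 7. With the Y-linked level as a covariate 11 fell, and 13 of 30 fell with no filter on low counts and 13 of 30 in the libraries of low Y-linked expression. Nr2e3 had a log2 fold change of -2.20, which was -3.02 without CD36-positive library 2 and -1.60 without CD36-negative library 2. Of 6 endothelial and pericyte genes 2 fell, Flt1 and Pecam1 (3 adjusted over the list alone; median -1.41, camera adjusted p = 0.0280, adjusted p = 0.151 with an estimated correlation). This list did not pass without CD36-positive library 3, 4 or 7 or CD36-negative library 4 or 8 (medians -0.99, -1.05, -1.26, -0.92 and -0.79), and with no filter on low counts the median over 23 members was 0.22. Homeostatic microglia genes showed 1 rise, Tgfbr1 (0.74), and 1 fall, Jun (-0.73), among 20 members (camera adjusted p = 0.441). P2ry12 (0.41) and Tmem119 (0.26), chosen after their values were seen, did not pass. Of 26 disease-associated microglia genes 3 rose and 1 fell (camera adjusted p = 0.188). Those that rose were Lilrb4a (1.06), Lpl and Spp1, osteopontin (1.60), and Itgax (-0.90) fell; Spp1 and Itgax were chosen after their values were seen.

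The remaining lists did not pass the camera test. Phagocytosis receptors rose in 4 of 29 members, among them Fcgr1 (0.97) and Itgav (0.81), and fell in 2 (camera adjusted p = 0.186). Of 15 complement genes 1 rose and 2 fell, C3 and Cfp, each at -1.55 (camera adjusted p = 0.961). MHC class I genes fell in 1 of 18 members, H2-Q7 (-0.79), whose close copies can share reads and leave its count uncertain (camera adjusted p = 0.116). The lysosome list had 1 rise in 35, Ctsc (1.02, camera adjusted p = 0.188), and the glycolysis list 1 fall in 18, Pfkp (-2.22, camera adjusted p = 0.188). The NRF2 list had 3 rises, Prdx1 (0.94) among them, and 1 fall, Gsr (-1.55, also in the monocyte list), in 24 (camera adjusted p = 0.961). The unfolded protein response list had 1 rise, Hsp90b1 (0.60), and 1 fall, Herpud1 (-0.73), in 23 (camera adjusted p = 0.961). The TGF-beta list had 2 rises in 13 (camera adjusted p = 0.441), Itgav and Tgfbr1. Among cell types, Müller glia and astrocyte genes rose in 1, Kcnj10 (1.39), and fell in 2 of 12 (camera adjusted p = 0.513). Inner retinal neuron genes fell in 2 of 9, Rbpms (-2.29) and Thy1 (camera adjusted p = 0.213). Platelet genes rose in 1, Pf4 (1.29, also in the list of macrophages of vessels and borders), and fell in 1 of 9, Rgs18 (-2.68, camera adjusted p = 0.606). Ribosomal protein (47 tested, camera adjusted p = 0.340), erythroid (6 tested, camera adjusted p = 0.606) and pigment epithelium genes (5 tested, camera adjusted p = 0.988) had 0 members past edgeR's threshold. Adjusted over the list alone, rises and falls numbered 6 and 4 for phagocytosis, 1 and 3 for complement, 0 and 2 for MHC class I, 1 and 2 for the unfolded protein response, 1 and 3 for Müller glia, 2 and 3 for inner neurons and 1 and 2 for platelets. For the other lists named in this and the previous paragraph as not passing camera, these counts equalled those over all genes.

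Y-linked genes divided the libraries in another way than the groups. Ddx3y was at 77.3 to 162 CPM in CD36-positive libraries 1, 2 and 3 and CD36-negative libraries 1 and 2, and at 6.77 to 17.8 CPM in the other 5. Within the 5 libraries of high Y-linked expression 33 genes were higher and 215 lower in CD36-positive cells, and within the 5 of low expression 137 and 467. Cd36 had log2 fold changes of 2.31 and 1.77 in these. The count of higher genes moved by over 1.5 times when CD36-positive library 3 (196) or CD36-negative library 4 (132), 7 (182) or 8 (197) was left out. With 1 library left out in turn, some genes named here as past the threshold lost their call while keeping their direction. These were Tgfbr1 and Nr2e3 in 7 of 10 fits, Pecam1, Ndufa4, Sqle, Mvd and Spp1 in 6, and Casp1, Txnip, Atp5k, Stab1 and Itgax in 5. Jun, Hsp90b1 and Ifi204 lost it in 4, Lipe in 3, Flt1 in 2, and Ccl7, H2-Q7 and Rgs18 in 1. Nothing in the labels says that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical in part, although Y-linked levels differed within each group.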

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

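All of the tests of explanations in this part, the counts over other splits included, and the tests by Y-linked expression were written down only after the results they bear on had been seen. Of 186 groups of 5 values examined for a single value far from the other 4, 18 were picked out, where chance gives about 1 in 20. Thy1, Apol7c, Ffar4 and Ccl17 were among these with 1 or 2 counts in 1 library and 0 in the others. A single value among zeros is always picked out, so the tally cannot be set against that rate.

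In CD36-positive library 1, Abca1 was at 558 CPM (other libraries of the group 236 to 299), Dppa3 at 34.6 (12.8 to 15.0) and S100a9 at 10.0 (0 to 2.14). In CD36-positive library 2, Nr2e3 was at 12 CPM (1.43 to 3.94) and Gzmb at 0.677 (0 to 0.143), and Thy1 and Apol7c at 0.113 each (0 in the others). In CD36-positive library 3, Ccl7 was at 303 CPM (19.4 to 37.0), Ndufa4 at 214 (157 to 172) and Itgae at 3.44 (0 to 0.677). In CD36-positive library 7, Ffar4 was at 0.0792 CPM and Ccl17 at 0.158 (0 in the others). In the CD36-negative group, Pltp was at 265 CPM (113 to 156) and Clec10a at 150 (75 to 94.8) in library 4, H2-Q7 at 191 (128 to 133) and Cyp51 at 44.2 (61.6 to 68.5) in library 2, Ccl12 at 250 (95.6 to 139) in library 8, and Msr1 at 56.9 (35.8 to 41.8) in library 1.

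The difference between CD36-positive and CD36-negative cells was itself compared between the 5 libraries of high and the 5 of low Y-linked expression, with an interaction term. In edgeR 0 genes passed (554 at an unadjusted p under 0.05). With the preset correlation 5 lists passed camera: MHC class II presentation (adjusted p = 2.14e-05), ribosomal proteins (0.00173), monocytes (0.00293), dendritic cells (0.00697) and MHC class I presentation (0.00697). With an estimated correlation their adjusted p ran from 0.358 to 0.839.

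The first pattern is the lower level of other leukocytes' markers in CD36-positive cells; if only the share of microglia differed, markers of every other type would move alike, but the neutrophil median lay 4.20 below the photoreceptor median on the log2 scale (difference -4.20, permutation over genes p = 0.0001, the smallest these can give), which argues against that. Over the CD36-negative libraries, 65 marker genes of neutrophils, T and NK cells, dendritic cells and monocytes correlated more within a type (mean 0.188) than between types (mean 0.020), a difference of 0.168 (permutation over genes p = 0.0002). This is consistent with cells of separate types in these libraries, as a hypothesis, and genes are not independent replicates. The CD11b and intermediate CD45 gate should remove most T cells. The T and NK cell list covers NK cells too, and how far the gate removes those was not examined. S100a8 and S100a9, abundant neutrophil transcripts chosen after their values were seen, reached only 95.7 and 117 CPM on average in CD36-negative libraries. Of 18 dendritic cell markers 12 fell and 1 rose. Among those that fell, Ccr7 was at 208 ± 54.9 CPM in CD36-negative and 7.04 ± 9.74 CPM in CD36-positive libraries. Flt3 was at 133 ± 40.0 and 2.73 ± 2.5 CPM, and both genes were chosen after their values were seen. A different state of CD36-negative microglia was not tested and stays open.

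The second pattern is lower Il1b in CD36-positive cells. After correction for GC content and transcript length its log2 fold change was -1.49 (adjusted p = 0.000644, edgeR), against -1.53 before, which argues against those trends as the whole cause. Neutrophils in the CD36-negative libraries cannot be told apart from a lower level within microglia. The Il1b excess of 91.4 CPM was 0.798 of the S100a9 excess. That ratio cannot decide, since CPM values of 2 genes are not corrected for transcript length and how much Il1b such cells carry is not measured here. Dendritic cells and monocytes, most of whose markers moved the same way, stay open too, although the monocyte marker Ccr2, chosen after its values were seen, was at 413 CPM in CD36-positive and 408 CPM in CD36-negative libraries; so does a difference in expression tied to CD36.

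The third pattern is the rise of cell cycle genes, which as a list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.330 with an estimated correlation). After the same correction 24 members were past the threshold (18 with the robust fit) with a median of 1.15, against 19 and 1.09 before, which argues against GC content and length. Without CD36-positive libraries 1 and 3 the median was 0.78 and 4 members passed, so a part carried by these libraries cannot be told apart from a difference of the group: the median kept its direction, while calls in this list fell further than those over all genes (188 higher against 303, 570 lower against 550). The loss of calls is not particular to them, since 7 members passed without CD36-negative library 4 alone, 8 without CD36-positive 3, 9 without CD36-negative 8, and 12 without CD36-positive 2 or CD36-negative 2 or 7. More division of CD36-positive cells was not tested otherwise and stays open.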

How the results depend on the processing

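The corrections for GC content and length, the settings by Y-linked expression, the fit without 2 libraries and the fit without lines at block edges were chosen after seeing the data. Against 303 genes higher in CD36-positive cells, the DESeq2 Wald test gave 533, the replicate block by description number 184, an adjusted p of 0.01 gave 90, the test against a log2 fold change of 1 gave 6, the correction for GC content and length 672, the fit without CD36-positive libraries 1 and 3 gave 188, and the libraries of high and low Y-linked expression 33 and 137. Leaving out each sample gave 132 to 380. Against 550 genes lower, the adjusted p of 0.01 gave 330, the test against a log2 fold change of 1 gave 214 and the libraries of high Y-linked expression 215; leaving out each sample gave 422 to 583. The stricter thresholds and the subsets call fewer by construction; otherwise the cause was not tested. The correction moved the median log2 fold change of all genes from 0.017 to 0.162 and the share of calls that were higher from 35.5% to 60.9%; with the robust fit, tried for that reason, the median was 0.056, the share 42.5% and the counts 347 and 470. Of the 853 calls, 661 were shared with the first correction and 640 with the robust one. The number of lists past the threshold, 13, fell to 4 with an estimated correlation and was 11 to 15 with each sample left out. Cd36 stayed higher and past the threshold in every alternative run, at 1.77 to 2.31, and at 2.04 to 2.19 with each sample left out. Itgam and Ptprc, which did not pass, changed sign: Itgam was at 0.07 with the replicate block by description number and 0.37 in libraries of high Y-linked expression, and Ptprc at -0.01 with voom, -0.06 without CD36-positive library 1 (-0.06 to 0.22 with each sample left out), -0.12 and -0.18 with the first and the robust correction, -0.11 in libraries of low Y-linked expression and -0.22 without CD36-positive libraries 1 and 3. Ccr2, which did not pass either, changed sign from 0.01 to -0.01 with no filter, -0.06 with the replicate block by title number and with the Y-linked level as a covariate, -0.17 with voom, -0.25 and -0.31 with the first and the robust correction, -0.39 in libraries of low Y-linked expression and -0.24 without CD36-positive libraries 1 and 3 (-0.28 to 0.14 with each sample left out). Same-numbered samples did not deviate together in every pair (correlations 0.029, 0.133, 0.099 and 0.101 for numbers 1, 2, 4 and 7, and only number 2 correlated best with its own), and the labels tie no number to an animal, so the numbers were not taken to pair the samples. Y-linked expression was high in both samples numbered 1 or 2 and low in both numbered 4 or 7, so a shared origin of same-numbered samples stays open. In the block by description number, CD36-positive library 3 and CD36-negative library 8 have no partner. Each is absorbed by its own term, so that contrast rests on numbers 1, 2, 4 and 7. With the block by description number, 12 photoreceptor genes fell (2 without the block), 0 endothelial genes fell (2), 0 oxidative phosphorylation genes rose (4), 8 type I interferon genes rose (4) and 13 cell cycle genes rose (19), and the endothelial list and that of macrophages of vessels and borders did not pass. Of the genes described, Lpl, Flt1, Pecam1, H2-Q7, Kcnj10, Atp5k, Ndufa4, Hsp90b1, Ccl7, Stab1, Mvd, Casp1, Txnip, Spp1 and Ms4a4c did not pass with this block and kept their direction. With the block by title number 11 photoreceptor genes fell and the counts were 271 higher and 585 lower. Of 100 splits into 5 and 5 (126 possible), only the real one reached 303 and 550 genes. The others gave at most 7 in 1 direction, for the split by Y-linked expression. They mix the groups, which widens the spread on each side, so they cannot exclude chance. Nor is it excluded for lists: 12 of 100 gave at least 13, the highest other 18. Depth limits genes with few counts, and the 2 shallowest libraries are both CD36-positive.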

Other observations

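Tests in this part were written after the results they bear on had been seen. Of 23 cholesterol synthesis genes 5 fell in CD36-positive cells and 18 did not pass, while Abca1 and Ch25h rose. The synthesis list passed with the preset correlation (camera adjusted p = 2.64e-06) but not with an estimated one (adjusted p = 0.131 with an estimated correlation). One hypothesis is a higher sterol content of the CD36-positive cells, which may lower targets of SREBP2 and raise those of LXR. For the second part, the cholesterol efflux and LXR list did not pass (camera adjusted p = 0.735, median log2 fold change 0.25), with 2 members higher and 2 lower. That list is not one of LXR targets alone: Nr1h2, 1 of the 2 lower members, encodes LXRβ itself, and the other is Pltp. Whether Abca1 and Ch25h, the 2 higher members, rose through LXR was not tested. The other 14 did not pass. Among them were Abcg1 (-0.03), Srebf1 (-0.25), Lpcat3 (-0.29), Mylip (0.25) and Apoe (0.30), chosen after their values were seen. The list therefore cannot decide the second part, and the hypothesis stays undecided. Markers of neutrophils, T and NK cells, dendritic cells and monocytes were lower in CD36-positive cells too (medians -5.72, -3.58, -2.81 and -2.24), and a share of such cells in the CD36-negative libraries was not tested for the synthesis genes and stays open. Lipids were not measured here.

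Haemoglobin gene Hba-a1 was at 705 CPM in CD36-positive library 3 and 261 CPM in CD36-negative library 1, and at 0.209 to 7.44 CPM in the other 8 libraries.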
